A study of Mus musculus with 8 samples.

How the data were processed

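The series holds 8 polyadenylated RNA libraries of mouse 46C cells, 4 from day 0 and 4 from day 5, 1 per group, with groups taken from the labels. For each day 5 library, the authors deposited estimated counts per gene (expected counts, not all whole numbers) and FPKM values, per the file headers. Genes under 0.01 FPKM are not listed there and were taken as 0. For day 0, the authors deposited a single table of RPKM values and estimated read counts per library, per the file headers. They also deposited, for day 5, comparison tables of KO with WT and of shMef2c with shCtrl, made by a Poisson-distribution method per the labels. Per the file headers these deposited tables hold log2 ratios, and adjusted p-values as a false discovery rate. In their values, the smallest absolute log2 ratio is 1 and the largest false discovery rates are 0.000993 and 0.001. Their expression columns equal the library FPKM values for all 2253 and 2758 genes within 0.005. The submitters' processing notes name HISAT, HISAT2, Bowtie, Bowtie2, RSEM and the mouse build mm9, with no role, order or version. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies have uncertain values.

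The day 5 files cover 21069 features, 1469 of them predicted by the authors and taking 6.15% to 7.09% of reads, and the day 0 table covers 19011 genes. Both share 17363. Of the day 0 symbols, 26 had been turned into dates by a spreadsheet and were restored through their gene identifier. Gene identifiers were found in a RefSeq table of the GRCm38.p6 assembly for 19547 day 5 and 18873 day 0 features. Since that assembly differs from mm9, it was used for names, chromosome assignment and gene order only, and no coordinates are given.

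Ratios were computed as log2((value + 1)/(value + 1)) on the deposited FPKM or RPKM values, for features with a mean of 1 or more over the pair. The pseudocount of 1 makes the ratio of scarce genes smaller than the ratio of their values. With 1 library per group there is no test and no p-value, and a gene was counted as higher or lower at 2-fold or more. In data simulated for KO and WT at day 5 by Poisson draws over 20292 genes, 200 genes were changed. They were drawn, as for day 0, from genes with a mean of 2 or more, so genes with a mean between 1 and 2 were not covered. Of the changed genes, 96.9% of the 64 changed 3-fold and 100% of the 62 changed 6-fold were called. None of the genes changed 1.5-fold was called, and 2 unchanged genes were. For KO and WT at day 0 (18372 genes), 98.3% of genes changed 3-fold, 100% of those changed 6-fold and 0 unchanged genes were called. In 10 draws with no change, counting error alone gave at most 5 calls in any of the 6 comparisons. Differences between cultures are not part of that error. Of 200 lists of unchanged genes drawn from these simulated data, 4.5% (day 5) and 6% (day 0) lay outside the random-list limits. Intervals on single ratios of reads are exact (Clopper-Pearson) 95% intervals and cover counting error only.

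Before the data were examined, 26 gene lists of cell types, pathways and chromosomes were fixed. They cover naive pluripotency, epiblast transition, neural progenitors, neuronal differentiation, synapse and channel genes, autism-associated genes, forebrain and midbrain and hindbrain patterning, germ layers, feeder fibroblasts, signalling, stress, imprinting, the 2-cell-like state, the Mef2 family and Y-linked genes. A list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. It is called outside the limits below the 2.5 or above the 97.5 percentile, as a description of these libraries. Lists with under 3 measured members got no percentile. For every list outside the limits, the median and the mean had the same sign. For comparisons of day 5 with day 0, ratios were centred on the median of all genes.

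Genes named in the text follow a rule, also set before the data were examined. It takes Mef2c and its family first, then the 10 highest and 10 lowest ratios per comparison (5 at day 0) with mean 1 or more, leaving out Gm, Rik, LOC and unnamed genes. It adds 2 to 4 members of each list with the largest ratios, and 5 genes each way for the overlap. The levels of named genes in other libraries were added after their values were seen. Lists given by a median alone have no members named, and the values of 1 further gene are not reported here. Overlap counts are set beside the number for independent lists. The pairs of the overlap have no control library in common.

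Alternatives were a pseudocount of 0.1, no filter or a mean of 5 or more, centring on the median, values rescaled to a common total (TPM), estimated counts with TMM factors of edgeR 4.0.16 or size factors of DESeq2 1.42.0, folds of 1.5 and 4, the requirement of both control libraries, and the authors' deposited tables. For the count settings, estimated counts were rounded, a prior count of 5 was added, and genes with 20 or more reads in the pair were kept. Chosen after the data were seen were the other control library of the day, leaving out genes of chromosomes 11, 14 and 17, leaving out predicted features and, for the comparison of days, the same members in each line. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.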

Results

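RNA-seq profiles of 8 cultures of the mouse embryonic stem cell line 46C were analysed, 1 library per group. Cells of 46C carry a green fluorescent protein reporter in the neural gene Sox1. The groups were wild type (WT), a line labelled LincNDIME_KO (here KO), a line with a control hairpin RNA (shCtrl) and a line with a hairpin RNA against Mef2c (shMef2c). Each was profiled at day 0, as stem cells on feeder fibroblasts with the cytokine LIF, and at day 5, as neural progenitor cells formed by aggregation in serum replacement medium. NDIME is a long intergenic noncoding RNA per the study's title, and Mef2c encodes a transcription factor of muscle and nerve cells. The title places both in one axis of neural differentiation and names autism, so the comparisons ask what each perturbation changes and how far the changes overlap. Estimated reads assigned to genes came to 26834802 (WT), 26493161 (KO), 25996204 (shCtrl) and 26616030 (shMef2c) at day 5. The day 0 libraries held 20883674 (WT), 20312032 (KO), 20769916 (shCtrl) and 20700342 (shMef2c). With 1 library per group, none of the differences has a replicate check, so no p-value is given and each statement describes these libraries. The difference between the control libraries WT and shCtrl serves as the yardstick.

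Mef2c was scarce in every library. At day 5 it was lower in KO and in shMef2c than in their controls. At day 0 it was close to WT in KO, and above shCtrl in the library labelled shMef2c. At day 5, Mef2c stood at 0.45 FPKM in WT (77 reads), 0.10 in KO (17 reads), 0.50 in shCtrl (82 reads) and 0.12 in shMef2c (20 reads). Its share of reads in KO was 0.224 times that in WT, with a 95% counting interval of 0.124 to 0.382. In shMef2c the share was 0.238 times that in shCtrl (0.138 to 0.392). The control libraries differed by a ratio of 1.1 (0.796 to 1.52). These intervals cover counting error only. The authors' deposited table gives Mef2c a log2 ratio of -2.17 for KO over WT and -2.06 for shMef2c over shCtrl. At day 0, Mef2c was at 0.23 RPKM in WT (29 reads) and 0.24 in KO (26 reads). It was at 0.16 in shCtrl (20 reads) and at 0.37 in the library labelled shMef2c (44 reads). That ratio of 2.21 (1.27 to 3.95) runs against the label, so the day 0 library is called "the library labelled shMef2c" below. No feature in the files carries the name NDIME, so its level was not measured by name and the deletion was not checked here. Among the other Mef2 genes, Mef2a stood between 4.56 and 6.76 FPKM and Mef2d between 6.28 and 9.42 FPKM at day 5. Mef2b stayed at 0.58 FPKM or less.

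The control libraries, which the labels give no reason to differ except for the hairpin, differed at day 5 in 128 genes by 2-fold or more, 93 higher and 35 lower in shCtrl. Rbp4, a retinol carrier of visceral endoderm and liver, stood at 3.16 FPKM in WT and 30.2 in shCtrl. Apoa1, the main protein of high-density lipoprotein, went with it at 3.00 and 22.1. Embryonic globin genes were also higher in shCtrl, with Hbb-bh1 at 22.3 against 3.73 and Hba-x at 11.1 against 0.95. Grb10, an imprinted growth regulator, was lower in shCtrl at 24.7 against 96.8. Leaving out Gm, Rik, LOC and unnamed genes, high ratios also belonged to Pga5 (37.6 against 6.58), Hba-a1 (10.1 against 1.24), Hesx1 (6.55 against 0.91), Sfrp5 (13.4 against 2.95), Snora78 (3.09 against 0, 7 reads against 0) and Snhg10 (2.88 against 0). Low ratios belonged to Pdf (0.58 against 4.51), Btg3 (0 against 2.27), Snora70 (0.61 against 3.73, 1 read against 6), Gstp2 (1.52 against 5.99), Acta2 (5.60 against 16.0), Pglyrp1 (0.25 against 2.11), Zfp296 (1.64 against 5.49), Dnmt3l (12.5 against 31.5) and Bc1 (2.73 against 7.39, 6 reads against 16). Among the gene lists, naive pluripotency was lower in shCtrl (median log2 ratio -0.44, 23 of 24 members below 0). Higher lists were neuronal differentiation (0.44), forebrain patterning (0.71), endoderm (0.59, or 0.39 with no filter on low values), neural crest and surface ectoderm (0.43, or 0.16 and inside the limits with no filter), synapse and channel (0.32) and imprinted genes (0.22). Lower lists were p53 targets (-0.26), midbrain and hindbrain patterning (-0.23, or -0.10 with no filter), proliferation (-0.21) and epiblast transition (-0.17, or -0.12 and inside the limits with a mean of 5 or more). In all, 11 of 25 lists lay outside the limits set by random lists of matched expression, so lying outside them is common between single cultures here and the size of a median matters more.

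The KO line asks what changes with the noncoding RNA deleted, and at day 5 it had higher pluripotency and endoderm genes and lower hindbrain, Notch and neural progenitor genes than WT. Naive pluripotency genes had a median log2 ratio of 1.31 over WT, with 16 of 25 members 2-fold or more higher and none lower by that size. Dppa2, a chromatin factor of early embryos, stood at 46.4 FPKM against 10.5. Esrrb, a receptor that sustains stem cell renewal, stood at 35.7 against 9.22. Endoderm genes had a median of 1.46, with 14 of 21 members 2-fold or more higher and 3 lower. Against shCtrl the endoderm median was 0.69, near the 0.59 between the control libraries, and Apoa1 was lower in KO (10.0 FPKM) than in shCtrl (22.1). Afp, the fetal serum protein alpha-fetoprotein, stood at 23.3 against 0.30, and Ttr, a thyroid hormone carrier, at 22.7 against 0.51. Cubn, an uptake receptor of visceral endoderm, stood at 19.9 against 1.18, while Cer1, a secreted inhibitor made by anterior endoderm, was at 0.14 against 12.6.

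In KO at day 5, neural progenitor genes had a median log2 ratio of -0.66, with 8 of 25 members 2-fold or more lower and 2 higher. The radial glia gene Fabp7 stood at 30.0 FPKM against 173.7 in WT, and the Notch effector Hes5 at 4.47 against 23.3. Neuronal differentiation genes had a median of -0.50 (-0.97 against shCtrl), with 10 of 34 members 2-fold or more lower. Among them, the transcription factor gene Neurod4 stood at 1.53 against 12.5. Midbrain and hindbrain genes had a median of -0.98 (-0.64 against shCtrl, -0.59 with no filter on low values), with 8 of 16 members lower. The lowest were the Hox genes Hoxb2 (6.53 against 49.3), Hoxb3 (2.93 against 24.8) and Hoxb1 (1.89 against 17.6). Notch targets had a median of -1.20 (-0.80 with no filter), with Lfng at 5.14 against 18.2 and Hey1 at 4.07 against 14.3. Forebrain genes had a median of 1.15 over WT (0.41 with no filter), with 5 of 7 members higher, such as Lhx2 (16.8 against 3.38) and Hesx1 (5.85 against 0.91). Against shCtrl instead of WT, the forebrain median was -0.012, so that direction depended on the control library.

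In KO at day 5, mesendoderm and mesoderm genes had a median log2 ratio of -0.74 (-0.28 with no filter), with 4 of 10 members 2-fold or more lower. The mesoderm regulator T stood at 0.35 FPKM against 40.5 and Gsc at 0.38 against 4.83. T lies on chromosome 17, which was lower as a whole in KO. Against shCtrl the mesendoderm median was -0.34 and inside the random-list limits. Epiblast transition genes (0.48) and BMP and TGF-beta targets (0.43, Lefty2 at 37.9 against 12.3) were higher. Wnt targets (-0.36, Wnt8a at 2.59 against 9.98) and heart and muscle genes (-0.37, Acta2 at 3.35 against 16.0) were lower. Inside the limits under another filter were the heart and muscle median, at -0.019 with no filter on low values, and the Wnt median, at -0.018 with a mean of 5 or more. The 2-cell-like list, genes of the mouse embryo at genome activation, had a median of 1.49, with 9 of 10 members higher. Zscan4f stood at 21.4 against 1.5, and the near-identical copies of Zscan4 make the split between its members uncertain. Imprinted genes had a median of -0.13, inside the limits, but -0.65 against shCtrl and -0.15 with TPM, both outside them. They held the lowest gene of the comparison over WT. Mest, a maternally imprinted gene of growth control, stood at 5.99 FPKM against 306 (397 against 20592 reads), and Grb10 at 3.06 against 96.8. Lists inside the limits were synapse and channel (-0.13), autism-associated genes (-0.04, 1 of 29 members 2-fold lower), neural crest and surface ectoderm (0.21), fibroblast feeder (-0.31), immediate early (0.11), proliferation (0.02), p53 targets (0.17), hypoxia and glycolysis (0.01), unfolded protein and amino acid stress (-0.14), interferon response (-0.03), the Mef2 family and neighbours (-0.07) and Y-linked genes (-0.39). Against shCtrl the p53 median was 0.50, outside the limits, and with a mean of 5 or more so was the neural crest and surface ectoderm median, at 0.44.

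Over all genes, 938 of 12832 differed by 2-fold or more between KO and WT at day 5, 520 higher and 418 lower. Against shCtrl 607 were higher and 720 lower, so which direction held more genes depended on the control library. Besides those named, and leaving out Gm, Rik, LOC and unnamed genes, the highest ratios in KO belonged to Srgn (37.4 against 1.92 FPKM), Stra8 (22.7 against 1.07), Tuba3a (36.5 against 3.23), Mael (16.9 against 1.40), Ctsh (27.7 against 2.95) and Fkbp6 (11.3 against 0.88). Stra8, Mael and Fkbp6 are genes of germ cells. With the same names left out, the lowest ratios also included Defa-rs2 (0.09 against 15.1) and Defa-rs4 (not listed and taken as 0 against 6.28, 43 reads), which share sequence with other defensin genes, as well as Nlrp4e (1.22 against 19.5), Vtn (2.29 against 24.7) and Samd3 (0.04 against 6.38). The authors' deposited table lists 2253 genes for this pair, 1151 higher and 1102 lower, on a ratio with no pseudocount and a Poisson-based test. It contains 927 of the 938 genes. Both use the same FPKM values and a 2-fold cut, and leaving out the pseudocount never makes a ratio smaller in size. That containment was therefore largely fixed in advance and is no independent check.

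The shMef2c line asks what changes with a hairpin RNA against Mef2c. At day 5 it had higher pluripotency genes and lower neural genes than shCtrl over most list members. Mef2c was lower there too, and whether that came before or after the neural change cannot be told from these libraries. Naive pluripotency genes had a median log2 ratio of 1.83 over shCtrl, with 23 of 25 members 2-fold or more higher. Dppa2 stood at 35.6 FPKM against 4.16, Tdgf1, a co-receptor for Nodal, at 69.7 against 11.4, and Dppa5a at 1642 against 295. Neural progenitor genes had a median of -1.62, with 20 of 25 members lower by that size and none higher. Hes5 stood at 0.57 against 36.0, Fabp7 at 11.6 against 233, the homeobox gene Dbx1 at 0.30 against 15.7 and Pax6, a master regulator of eye and forebrain, at 0.21 against 12.3. Neuronal differentiation genes had a median of -1.81, with all 34 measured members below 0 and 27 of them 2-fold or more lower. The neurofilament genes Nefm (1.27 against 25.6) and Nefl (7.59 against 94.4) were among them, with Neurod4 (0.17 against 14.6). Synapse and channel genes had a median of -0.47, 5 of 16 lower, such as Syp (1.12 against 7.21) and Snap25 (0.54 against 4.65).

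In shMef2c at day 5, mesendoderm and mesoderm genes had a median log2 ratio of 0.99 (0.51 with no filter), with 7 of 15 members 2-fold or more higher and none lower. The caudal homeobox genes Cdx2 (17.3 against 1.06 FPKM) and Cdx1 (5.70 against 0.28), as well as Mixl1 (5.25 against 0.61) and Eomes (14.7 against 3.27), led it. Forebrain genes had a median of -1.52, with 4 of 5 lower, such as Lhx2 (0.31 against 6.12) and Otx1 (0.07 against 2.76). Against WT the forebrain median was -0.48 and inside the limits. Midbrain and hindbrain genes went both ways around a median of -0.21, with Fgf8 at 32.6 against 6.73 and Phox2a at 0.71 against 7.71. Against WT that median was -0.62, and with a mean of 5 or more it was -0.77, both outside the limits. The endoderm median was -0.24, inside the limits, but 0.79 against WT and -0.46 with a mean of 5 or more, both outside them, so its direction depended on the control library. Wnt targets (0.25, or 0.21 and inside the limits with no filter, Notum at 9.41 against 1.89) and BMP and TGF-beta targets (0.60, Nodal at 32.5 against 5.38) were higher. Notch targets (-1.0, or -0.66 with no filter, Nrarp at 6.37 against 32.4) were lower, and epiblast transition genes were higher (0.64, Etv5 at 66.2 against 18.1).

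Among the remaining lists, the 2-cell-like genes had a median log2 ratio of 1.54 in shMef2c at day 5 (0.59 with no filter), with 4 of 5 members higher and Zscan4c at 7.07 FPKM against 0.53. Imprinted genes had a median of -0.65 (-0.18 against WT), with 7 of 20 members 2-fold or more lower. Cdkn1c, an imprinted inhibitor of the cell cycle, had the lowest ratio of all genes, 2.85 against 127, while Grb10 stood at 122 against 24.7. Y-linked genes (0.74) and p53 targets (0.45, Phlda3 at 39.4 against 22.4) were higher and unfolded protein and amino acid stress genes (-0.26) lower. Against WT, the p53 median was 0.12 and the stress median -0.09, both inside the limits. Inside the limits were autism-associated genes (-0.11, 1 of 31 members lower, Ebf3 at 0.25 against 6.00), heart and muscle (-0.04), neural crest and surface ectoderm (-0.23), fibroblast feeder (-0.14), immediate early (0.08), proliferation (0.13), hypoxia and glycolysis (-0.05) and interferon response (0.17). Against WT the immediate early (0.27) and interferon (0.46) medians were outside the limits. On estimated counts with TMM factors so were the autism-associated (-0.21), neural crest (-0.84) and endoderm (-0.36) medians. The Mef2 family and neighbours had a median of -0.20, yet its member Nr2f1, a nuclear receptor of neural patterning, stood at 1.43 against 35.1, and at 13.4 against 42.0 in KO.

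Over all genes, 1208 of 13041 differed by 2-fold or more between shMef2c and shCtrl at day 5, 585 higher and 623 lower. Against WT 512 were higher and 414 lower, so here too the balance depended on the control library. Leaving out Gm, Rik, LOC and unnamed genes, of which unnamed ones had the highest ratios, further genes with high ratios were Gstp2 (26.2 against 1.52 FPKM), Lefty2 (65.5 against 6.99), Lefty1 (221 against 26.6), Ass1 (112 against 13.2), Defa-rs2 (108 against 13.4), Mylpf (119 against 15.9), Dnmt3l (90.7 against 12.5) and Hspb1 (184 against 26.3). Lefty1 and Lefty2 are inhibitors of Nodal signalling. Among the low ratios were also Hbb-bh1 (0.35 against 22.3), Nkx6-2 (3.54 against 68.0) and Ly6h (2.97 against 54.3). With the ratio required against both control libraries, 747 genes remained of the 1208. The authors' deposited table lists 2758 genes for this pair, 1229 higher and 1529 lower, and contains 1200 of the 1208. As for KO, that containment is no independent check.

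**Figure D1:**
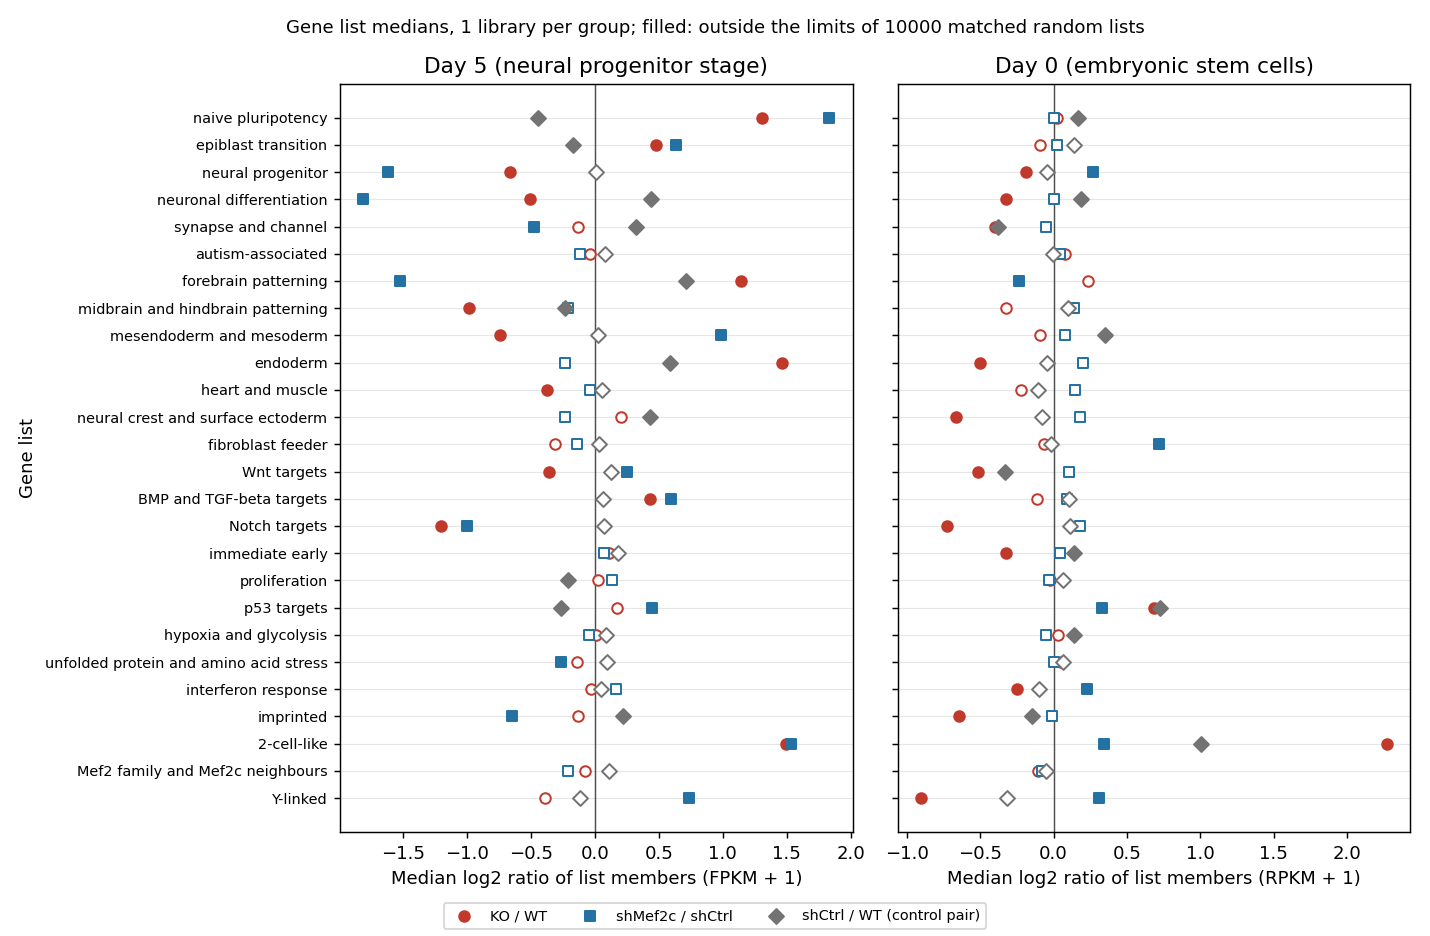
Median log2 ratio (x axis, FPKM + 1 at day 5 and RPKM + 1 at day 0) of 26 gene lists (y axis) for KO over WT (circles), shMef2c over shCtrl (squares) and the control pair shCtrl over WT (diamonds), with 1 library per group. Filled points lie outside the central 95% of 10000 random lists of matched expression, as the naive pluripotency medians of 1.31 (KO) and 1.83 (shMef2c) do at day 5, beside -0.44 for the control pair.

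The title's axis raises the question of how far the KO and shMef2c lines change alike, and at day 5 70.0% of genes had ratios of the same sign. These pairs have different control libraries. Of 12519 genes tested in both, 215 were 2-fold or more higher in both, against 17.3 for independent lists, and 176 were lower in both, against 19. Opposite directions were held by 42 genes, against 36.3. Genes of a cell state move together, so cultures with a like change of state would exceed the number for independent lists. The excess therefore does not test the axis. The log2 ratios had a Pearson correlation of 0.55 and a Spearman correlation of 0.56 across genes, which are not independent replicates. Higher in both were Zscan4c and Zscan4f, the water channel gene Aqp3 (11.1 against 1.33 FPKM in KO and 11.4 against 1.23 in shMef2c), the folate receptor gene Folr1 (47.8 against 9.01 and 27.1 against 4.91) and Gstp2 (30.0 against 5.99 and 26.2 against 1.52). Lower in both were Fabp7, Neurod4, the imprinted gene Nnat (3.38 against 22.5 and 2.93 against 34.5) and Tmed2, which was listed in neither line and taken as 0, against 5.42 and 5.58. Higher in KO and lower in shMef2c were Rbp4 (22.9 against 3.16, and 4.55 against 30.2), Lhx2, Ttr, Hesx1 and Apoa1. Lower in KO and higher in shMef2c were Grb10, Defa-rs2, Defa-rs4, Wnt8a and Arg1 (0.97 against 5.81, and 30.3 against 9.53). Among the genes named with opposite directions, Rbp4, Hesx1, Apoa1, Grb10 and Ttr also differed by 2-fold or more between the control libraries. Ttr stood at 0.51 FPKM in WT, 3.97 in shCtrl and 0.71 in shMef2c.

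**Figure D2:**
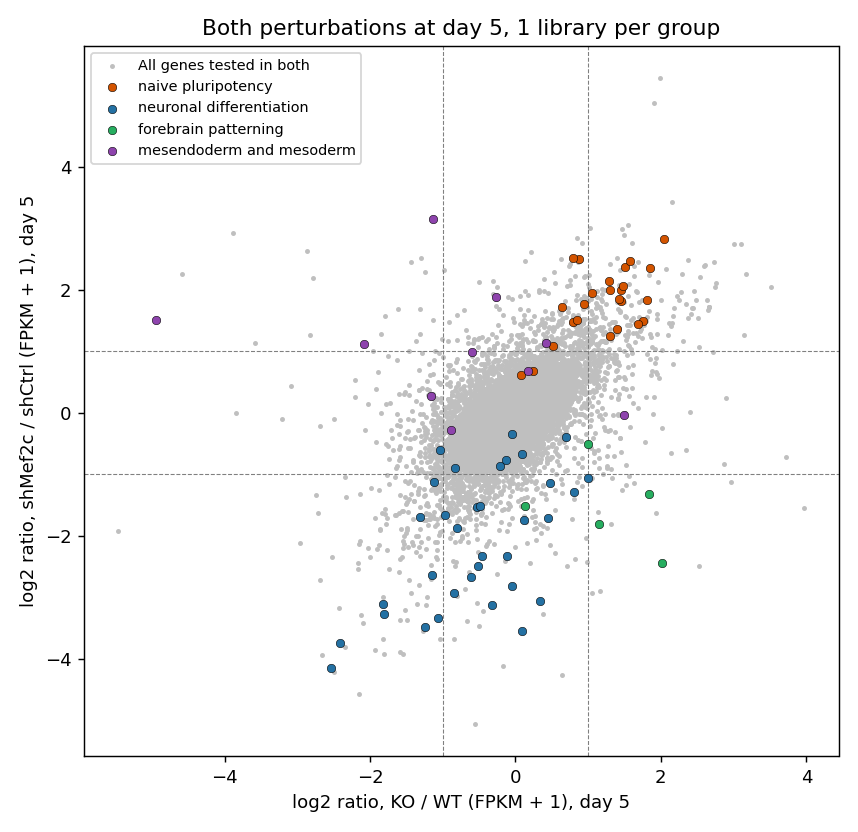
Log2 ratio of FPKM + 1 for KO over WT (x axis) and shMef2c over shCtrl (y axis) at day 5, 1 point per gene and 1 library per group, with dashed lines at 2-fold. Members of 4 lists are coloured. Naive pluripotency genes lie at the upper right, neuronal genes lie at the bottom with KO ratios on both sides of 0, and forebrain genes lie right of 0 and below 0.

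At day 0 the KO library differed from WT in 352 of 12002 genes by 2-fold or more, 162 higher and 190 lower, with no shift of the pluripotency list. Naive pluripotency genes had a median log2 ratio of 0.03, with 2 of 25 members lower, Dppa3 (16.0 RPKM against 84.9) and Lin28a (25.4 against 71.9). Dppa3 was also lower in shCtrl (20.6). The 2-cell-like list was the highest, with a median of 2.27 (1.13 with no filter) and 7 of 8 members 2-fold or more higher. Among genes with names other than Gm, Rik or LOC symbols, it held 4 of the 5 highest ratios, Zscan4f (27.1 against 1.7), Zscan4b (14.1 against 0.69), Zscan4c (11.9 against 0.78) and Zscan4d (9.92 against 0.75), followed by Rhox10 (5.55 against 0.39). The control pair had a median of 1.00 for this list (0.20 with no filter), with Zscan4f at 6.70 in shCtrl. The lowest genes were Klhl13 (25.5 against 286), Mest (1.90 against 26.6), Usp26 (0.51 against 10.8), Ina (3.84 against 23.9) and Lefty1 (5.09 against 30.2). Usp26 was also low in shCtrl (0.29), whereas Mest stood at 36.0 there.

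Imprinted genes at day 0 had a median log2 ratio of -0.64 in KO, with 15 of 18 members below 0, among them Peg10 (11 against 27.9 RPKM) and Igf2 (5.56 against 13.9). Neural crest and surface ectoderm genes had a median of -0.66, led by the epithelial genes Krt18 (1.95 against 9.94), Krt19 (1.97 against 9.75), Krt8 (3.06 against 11.1) and Epcam (4.85 against 15.8). With no filter on low values that median was 0.019. Further lists below 0 against both control libraries were Notch targets (-0.73 over WT, or -0.21 with no filter), neuronal differentiation (-0.32, -0.099 with no filter, or -0.11 and inside the limits with a mean of 5 or more), immediate early (-0.32, Fos at 48.6 against 75.7), interferon response (-0.25, Oasl2 at 9.90 against 31.9) and Y-linked genes (-0.90, or -0.54 with no filter, Eif2s3y at 29.6 against 57.4). Wnt targets (-0.52), endoderm (-0.50), synapse and channel (-0.40) and neural progenitor genes (-0.19) were below 0 over WT but inside the limits against shCtrl. With no filter they stood at -0.18, -0.037, -0.020 and -0.046, all but the Wnt targets inside the limits, and with TMM factors the Wnt median was -0.23 and inside. The Wnt targets Tcf7 (18.7 against 36.7) and Axin2 (7.80 against 14.1) lie on chromosome 11, whose genes were high in the WT library of day 0. For p53 targets the median was 0.69 over WT and -0.15 over shCtrl, a reversal that followed the WT library. Against shCtrl, 216 genes differed by 2-fold or more, and 131 did so the same way against both controls.

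The library labelled shMef2c differed from shCtrl at day 0 in 28 of 12103 genes, 16 higher and 12 lower, fewer than the 151 genes (90 higher, 61 lower) that separated shCtrl from WT. Its direction cannot be tied to lower Mef2c, since Mef2c was higher in that library as a whole. Feeder genes were higher there too, so whether stem cells or feeder cells gave the Mef2c reads cannot be told. Mef2c in the stem cells alone is thus not known. Among genes with names other than Gm, Rik or LOC symbols, the highest were Hist2h3c1 (2.36 RPKM against 0), the chemokine genes Ccl6 (4.55 against 1.28) and Pf4 (7.83 against 2.83), H2-Q6 (2.45 against 0.57) and Anxa8 (9.59 against 3.82). The lowest of these were Hist1h4n (0.06 against 3.14), the imprinted gene Phlda2 (24.5 against 66.2), Otx2 (1.01 against 4.02), Spink1 (0.49 against 2.09) and Cox20 (6.77 against 15.0). Histone and H2-Q genes have near-identical copies, so their values are uncertain. The fibroblast feeder list had a median log2 ratio of 0.72, with 21 of 21 members above 0 and none 2-fold, such as Lum (2.79 against 1.02), Timp3 (34 against 18.2) and Dcn (16.4 against 8.87). Beside it stood p53 targets (0.33), 2-cell-like genes (0.34), Y-linked genes (0.31), neural progenitor genes (0.27), interferon response (0.23) and forebrain genes (-0.23, 3 members). The forebrain median was above 0 under 4 other settings, the Y-linked median was -0.0027 against WT and 0.27 and inside the limits with TMM factors, and the interferon median was -0.033 with a mean of 5 or more. Against WT the neural progenitor (0.18) and interferon (0.15) medians were inside the limits, as was the 2-cell-like median (0.15) with no filter. Naive pluripotency was at 0.00, and at 0.15 and outside the limits against WT. Of 11771 genes tested in both day 0 comparisons, 3 were 2-fold or more higher in both (0.145 for independent lists), 1 was lower in both (0.124) and 1 went opposite ways. Those higher were Gm41885, Gm10698 and Gm21312, the lower was 0610010B08Rik and the last Gm14288, named outside the rule for gene names after their values were seen. The log2 ratios of the day 0 comparisons had a Pearson correlation of 0.20 and a Spearman correlation of 0.17 across genes.

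Between the control libraries at day 0, p53 targets were higher in shCtrl by a median log2 ratio of 0.73, with 7 of 17 members 2-fold or more higher, such as Phlda3 (40.3 against 15.8 RPKM), Bbc3 (15.2 against 5.63) and Perp (21.4 against 8.43). Mesendoderm and mesoderm genes were also higher (0.35, Cdx1 at 16.1 against 5.22), and synapse and channel genes lower (-0.38, Grin1 at 3.72 against 7.78). With no filter on low values these medians were 0.018 and -0.014, both inside the limits. In all, 10 of 25 lists lay outside the limits. Leaving out Gm, Rik and LOC symbols, the highest genes were Hist1h4n (3.14 against 0), Zbed5 (45.4 against 12.7, 794 reads against 512), Mup6 (6.85 against 1.31), Rtkn (13.1 against 3.60) and D1Pas1 (10.2 against 2.76). The lowest were Usp26 (0.29 against 10.8), Enpp3 (0.90 against 6.57), Dppa3 (20.6 against 84.9), Pnma5 (2.86 against 12.5) and Hist1h4m (0 against 2.28).

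Neighbouring genes on chromosome 14 were lower together in the KO line on both days. In gene order of the GRCm38.p6 assembly, the block between Zfp219 and Mtrf1 was set from KO against shCtrl at day 5, by windows of 25 genes with a median of -0.5 or lower. Relative to all genes, its median log2 ratio over WT was -0.85 at day 5 (188 genes) and -0.68 at day 0 (185 genes). The rest of the chromosome stood at 0.09 and 0.10. For shCtrl over WT the block stood at -0.00 and 0.02. In shMef2c over shCtrl at day 5, a run of windows from Arhgef19 to Fbxo2 on chromosome 4 was higher by up to 1.14, and windows on chromosome 6 by up to 0.69, with 36.3% of the windows of that chromosome above 0.2. Over WT at day 5 the chromosome 6 windows reached 0.45, with 25.7% above 0.2. For shCtrl over WT at day 5, 9.32% of them were below -0.2 and 1.83% above 0.2. Chromosome 6 already differed at day 0, with 12.1% of windows above 0.2 for the library labelled shMef2c over shCtrl (up to 0.26), 27.6% for shCtrl over WT (up to 0.43) and 35.3% for the library labelled shMef2c over WT (up to 0.57). Windows of chromosome 4 in KO over WT reached 0.70 at day 5, while on day 0 none passed 0.23 in KO over WT. In the library labelled shMef2c at day 0 they reached 0.16 over shCtrl and 0.25 over WT. Chromosome 17 as a whole was lower in KO, with a median of -0.30 at day 5 and -0.23 at day 0. At day 0, chromosome 11 was lower than in WT in the other libraries, with -0.41 in KO, -0.45 in shCtrl and -0.48 in the library labelled shMef2c. At day 5 it had a median of -0.13 in shMef2c over shCtrl, with 27.8% of windows below -0.2, and 2.41% over WT. Without genes of chromosomes 11, 14 and 17, the counts of 2-fold genes were 748 for KO and 1026 for shMef2c at day 5. For KO at day 0 the count was 253, of which 58.5% were higher in place of 46.0%. Chromosomes 4 and 6 were kept, so the 1026 genes still include those of the runs of shMef2c.

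**Figure D3:**
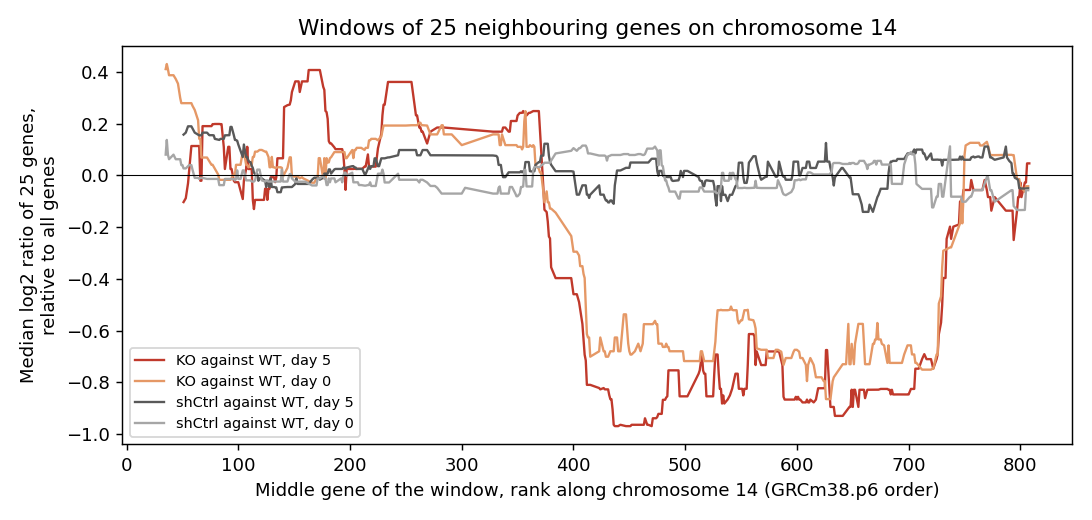
Median log2 ratio of windows of 25 neighbouring genes, relative to all genes (y axis), by the rank of the middle gene along chromosome 14 in the GRCm38.p6 assembly (x axis), for KO over WT and shCtrl over WT on each day, 1 library per group. The KO windows lie between about -0.5 and -1 over the block on both days (block medians -0.85 and -0.68), while the shCtrl windows stay near 0.

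The comparison of the days asks how far each line left the stem cell state. In each line, stem cell genes were lower and neural progenitor genes higher at day 5. Stem cell genes fell by less in KO and in shMef2c than in WT and shCtrl. Neural progenitor genes rose least in shMef2c, whose day 0 library is the one labelled shMef2c. The tables of the days were normalised separately, so the values here are relative to the median of all genes. The filter was set in each line, so the members measured differ between lines, and medians over the same members (mean of 1 or more over all 8 libraries) are given beside. Naive pluripotency genes had a median log2 ratio of -2.87 in WT, -1.86 in KO, -3.54 in shCtrl and -1.43 in shMef2c. Neural progenitor genes stood at 2.49, 2.06, 2.34 and 1.00 in the same order (22, 24, 24 and 16 members), and at 2.39, 2.05, 2.37 and 0.40 over the same 24 members. Neuronal differentiation genes stood at 1.94, 1.94, 2.28 and -0.00 (31, 26, 34 and 20 members), and at 1.88, 1.75, 2.40 and 0.11 over the same 32 members. Both values of shMef2c lay inside the random-list limits. In all 4 lines, 10 lists lay outside the limits in the same direction, and 9 did over the same members, without the midbrain and hindbrain list (0.46 in KO, inside the limits). Lower at day 5 were naive pluripotency, fibroblast feeder (-2.38 in WT, -1.60 in shCtrl), interferon response, immediate early and hypoxia and glycolysis genes. Higher at day 5 were neural progenitor, epiblast transition, midbrain and hindbrain, endoderm and imprinted genes. Endoderm medians were 0.75 in WT, 2.55 in KO, 1.79 in shCtrl and 1.38 in shMef2c, and 0.73, 2.68, 1.12 and 0.75 over the same 19 members. In numbers of genes, WT had 1836 higher and 1762 lower by 2-fold or more, and shCtrl 1863 and 1862. KO had 1211 higher and 1176 lower, and shMef2c 1136 and 1152.

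Counted over the 26 lists and the 4 comparisons of a perturbed line with its control, 48 of 104 medians lay outside the random-list limits, where 5% would for lists of unrelated genes. Between the control libraries, 11 of 25 lists lay outside the limits at day 5 and 10 of 25 at day 0. That share is similar, so the count alone does not set the perturbed lines apart. At day 5, 11 of 13 such lists in KO and 12 of 15 in shMef2c lay outside them in the same direction against both control libraries. At day 0 the counts were 8 of 13 for KO and 4 of 7 for the library labelled shMef2c. Larger as well than the difference between the control libraries were 10 of the 11, 10 of the 12, 8 of the 8 and 1 of the 4. The 2-cell-like list at day 5 and the forebrain list at day 0 had under 3 measured members in the control pair. With no control median to be set against, they were left out of the lists counted as larger. Lists shared by KO and shMef2c at day 5 under both controls were naive pluripotency, epiblast transition, BMP and TGF-beta targets and 2-cell-like genes (higher) and neural progenitor, neuronal differentiation and Notch targets (lower).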

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

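The results in the next paragraph had opposite directions between lines or between days. With 1 library per group, none of these differences was tested, and the choice of which to weigh followed the values. All tests in this part were chosen after the values were seen, except the share of genes nearly absent at day 0.

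Mef2c had a log2 ratio over shCtrl of 0.24 in the library labelled shMef2c at day 0 and -0.42 in shMef2c at day 5, a difference of 0.66. At day 5, forebrain genes had a median of 1.15 in KO and -1.52 in shMef2c (difference 2.66), mesendoderm and mesoderm genes -0.74 and 0.99 (difference -1.73) and Wnt targets -0.36 and 0.25 (difference -0.61). Against the other control library the forebrain medians were -0.012 and -0.48, both inside the random-list limits, and the mesendoderm median in KO was -0.34, also inside. With no filter the forebrain median in KO was 0.41 and the mesendoderm medians were -0.28 and 0.51. At day 0, KO and the library labelled shMef2c went opposite ways in neural progenitor genes (-0.19 and 0.27, difference -0.45), interferon response (-0.25 and 0.23, difference -0.48) and Y-linked genes (-0.90 and 0.31, difference -1.21). Against the other control, neural progenitor genes stood at -0.15 and 0.18, both inside the limits, the interferon median was 0.15 and inside the limits in the library labelled shMef2c (-0.033 with a mean of 5 or more), and its Y-linked median was -0.0027. Between the days, endoderm genes in KO stood at -0.50 at day 0 and 1.46 at day 5 (difference -1.97). Against shCtrl these medians were -0.016, inside the limits, and 0.69. Neural progenitor genes stood at 0.27 in the library labelled shMef2c at day 0 and at -1.62 in shMef2c at day 5 (difference 1.89).

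The pattern weighed first is the higher pluripotency and lower neural genes of both lines at day 5. Spread of the size seen in the single pair of control cultures (a median of -0.44) is argued against by the smallest naive pluripotency median over the 4 pairings with a control, 1.31. The same holds for the neural lists in shMef2c, whose medians nearest to 0 over its pairings were -1.62 (neural progenitor) and -1.55 (neuronal differentiation). In KO these were -0.55 and -0.50. The control cultures differed by 0.44 for neuronal genes, so the lower neuronal genes in KO cannot be told apart from such spread. For neural progenitor genes they differed by 0.013, so the -0.55 exceeded that list's own control difference. It was close in size to the 0.44 of other lists, and with a single control pair the lower neural progenitor genes in KO stay undecided. If undifferentiated cells carried over from day 0 were the whole cause, the share of such cells given by pluripotency genes would match the share that neural genes need. It was 19% (95% interval over genes 12.4 to 26.6) against 45.2% (30.2 to 58.2) in KO. In shMef2c it was 27.9% (16.3 to 35.4) against 83.1% (74.5 to 99.1). The intervals cover list members, not differences between cultures, and carried-over cells were given the day 0 levels of the control line. In shMef2c the gap argues against a mix of such cells with day 5 cells as the whole cause, on tables normalised separately by day. Undifferentiated cells with pluripotency levels below those of day 0 were not covered. In KO the share test decides nothing, since the lower neural progenitor genes there are undecided themselves. A test set before its result, the percent of genes nearly absent at day 0 that were 2-fold higher, gave 2.04% in KO and 2.69% in shMef2c and fell between its bounds, so it decided nothing; the share test was added only then, and carry-over may still be part of the pattern. Loss of NDIME or of Mef2c stays open as a candidate explanation. With 1 library per group, it cannot be told apart from differences between single lines or cultures. Whether the lower Mef2c of KO and shMef2c at day 5 came before or after the lower neural genes cannot be told either.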

How the results depend on the processing

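The other control library, the exclusion of chromosomes 11, 14 and 17, that of predicted features and the same members for the comparison of days were chosen after the data were seen. No paired analysis was possible because each group has 1 library and the labels carry no replicate numbers, as far as comparisons within a day go. Days were compared within each line, and no test over the 4 lines was run, since they differ in treatment and the days were normalised separately. The cause of each move below was not tested, except that other folds and filters change which genes can count. Counts are of genes at 2-fold or more, in the order KO over WT at day 5, shMef2c over shCtrl at day 5, KO at day 0, the library labelled shMef2c at day 0, shCtrl over WT at day 5 and at day 0, and shared genes of KO and shMef2c at day 5 and at day 0 (as reported 938, 1208, 352, 28, 128, 151, 391 and 4).

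Estimated counts with TMM gave 2400, 2861, 1032, 202, 720, 512, 1006 and 37, and with DESeq2 size factors 2400, 2858, 1031, 202, 742, 512, 1006 and 37. At 1.5-fold there were 2564, 3178, 1560, 318, 675, 814, 1245 and 76, and at 4-fold 116, 202, 39, 5, 14, 5, 32 and 1. A mean of 5 or more left 502, 623, 204, 7, 57, 83, 226 and 0. A pseudocount of 0.1 gave 1459 for KO at day 5, 653 for KO and 93 for the library labelled shMef2c at day 0, 330 and 304 for the control pair, and 642 and 19 shared genes. TPM values gave 583 for KO at day 0, 80 for the library labelled shMef2c, 218 and 264 for the control pair and 16 shared genes at day 0. Both controls were passed by 747 genes for shMef2c at day 5, and by 131 and 8 at day 0. The other control gave 216 and 313 genes at day 0, and 20 shared genes at day 0. The authors' deposited table lists 2253 and 2758 genes at day 5. The share of higher genes for the library labelled shMef2c at day 0 was 57.1% as reported and 70.3% with TMM or DESeq2 factors. The other counts run stayed within 1.5 times of those reported.

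Of 69 list calls (control pair included), 65 stayed outside the limits with TPM, 57 with TMM or DESeq2 factors or no filter, 67 with the smaller pseudocount and all 69 with centring. With a mean of 5 or more, 56 of 61 did, and 36 of 48 with the other control. Signs turned as follows. With no filter, neural crest genes in KO at day 0 stood at 0.019, forebrain genes in the library labelled shMef2c at 0.057 and neuronal genes of the control pair at day 0 at -0.014. That forebrain median was 0.22 with TPM and 0.31 with TMM and with DESeq2 factors, and the neuronal one -0.12 with TPM. Interferon genes in the library labelled shMef2c stood at -0.033 with a mean of 5 or more. With the other control, forebrain genes in KO at day 5 stood at -0.012, p53 targets in KO at day 0 at -0.15 and Y-linked genes in the library labelled shMef2c at -0.0027. The number of lists outside the limits was 44 to 54 (48 as reported), and that of lists shared by all lines between the days was 10, or 9 over the same members. Depth limits scarce genes such as Mef2c, at 17 to 82 reads.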

Other observations

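All tests in this part were chosen after the values were seen.

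At day 5, 14 of 20 imprinted genes were within 2-fold between KO and WT, and 19 of 21 between shCtrl and WT. The 4 named here were picked for their spread. Mest stood at 306 FPKM in WT, 5.99 in KO, 175 in shCtrl and 45.6 in shMef2c. Grb10 stood at 96.8, 3.06, 24.7 and 122 in the same order, Cdkn1c at 88.2, 59.8, 127 and 2.85, and Igf2 at 56.9, 49.4, 195 and 56.2. At day 0 the KO library already had little Mest, at 1.90 RPKM beside 26.6 in WT, 36.0 in shCtrl and 20.6 in the library labelled shMef2c. Dppa3 at day 0 stood at 84.9 RPKM in WT and between 16.0 and 20.6 in the other libraries.

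The block on chromosome 14 was lower in the KO libraries of both days. Scaling of the whole library moves all genes alike and cannot by itself set a block apart. The gap of -0.78 between the block and the other genes of chromosome 14 at day 0 is therefore no separate test of it. A state of differentiation that differs at day 5 is argued against by the block's median of -0.68 over WT at day 0. Fewer copies of the block in the KO line may explain it: for a block set from the day 5 libraries against shCtrl, 98.3% of its genes with a mean of 5 or more were below WT at day 0. Their median ratio to WT was 0.567 at day 0 and 0.518 at day 5, DNA was not analysed here, and lower transcription of the whole block stays open.

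In the WT library of day 0, chromosome 11 genes were higher and p53 targets lower than in the other lines. Feeder cells are argued against by the feeder list's median of -0.023 for shCtrl over WT. Extra copies of chromosome 11 in that culture stay open: at least 97.1% of its windows of 25 genes were below -0.2 for KO and for shCtrl over WT, which restates the shift of the chromosome and tests nothing, and DNA was not analysed here. The position of p53 targets on chromosome 11 does not account for them, as the median was 0.84 without the 1 member on that chromosome, and the WT library of day 5 showed no such shift of chromosome 11 (0.06 for shCtrl over WT). Why p53 targets were lower stays open, and no biological explanation was tested.

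Feeder genes at day 0 were higher by a median of 0.72 in the library labelled shMef2c, beside Mef2c at 44 reads against 20 in shCtrl. Which cells gave those Mef2c reads cannot be told from RNA of the whole culture. Autism-associated genes lay inside the random-list limits in all 6 comparisons, with medians between -0.11 and 0.08. On estimated counts with TMM or DESeq2 factors the shMef2c median at day 5 was -0.21 and outside them.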
